A study of Mus musculus with 48 samples.

How the data were processed

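Expression was measured in mouse hippocampus and amygdala on 48 one-colour Affymetrix oligonucleotide arrays, each hybridised with biotin-labelled cRNA made from total RNA. Per the labels, 26 arrays came from hippocampus and 22 from amygdala, and the arms were CS, FC and NH. The labels do not spell the arms out. From the series title, which concerns associative and nonassociative learning, they were read as exposure to the conditioned stimulus alone, fear conditioning and naive home cage animals, and the label codes are kept throughout. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these arrays, which may in part be technical. Array titles carry a number, used here as the replicate name, and no number occurs in more than 1 arm of a tissue. The amygdala numbers are longer. Each begins with the number of its processing batch, and the rest can be read as a pair of numbers. Some of these also name a hippocampus array, and then in the same arm. Amygdala arrays may therefore each pool a pair of animals, and the tissues may share animals. The labels do not say so, and no such link entered a fit.

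The deposited values are intensity on a linear scale, 1 per probe set and array. They were made with RMA (robust multi-array average), per the submitters' processing notes. RMA as generally described corrects background, makes the intensity distributions of the arrays alike and summarises the probes of a set, so a change shared by most transcripts would not be visible in such values. The version of RMA and its settings are not given in the sources used here. Array medians of the deposited intensity ranged from 76.4 to 80.5 in hippocampus and from 52.2 to 56.0 in amygdala, so the tissues appear to have been normalized separately. This is read from the values and not stated in a label. A planned test of amygdala against hippocampus in NH arrays was therefore not run, and tissue markers are described only by their percentile within each array. Tests of whether a difference between arms differed between the tissues were run, although the plan tied them to a common scale. A constant factor between the tissues cancels in them on the log2 scale, but a normalization that treated low and high intensities differently in each tissue would not.

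The log2 of the deposited intensity was taken and nothing was added to it. Of 12488 probe sets, 66 were array controls and were left out. According to the platform annotation used here, 10855 probe sets name 1 gene (8252 symbols), 396 name several and 1237 name none. Of those that name 1 gene, 10839 had their gene identifier in the RefSeq gene table of assembly GRCm38.p6, and no symbol needed changing. Only probe sets that name 1 gene are named in the text. Arc is not named by any probe set in that annotation. Within each tissue the 40% of probe sets with the lowest mean were left out, which left 7453 for testing. Ier2, Homer1 and the second probe sets of Fos and Egr1 lay below that limit in both tissues, and Egr2 lay below it in hippocampus. Arrays of a tissue correlated with each other at r from 0.982 to 0.999 in hippocampus and from 0.987 to 0.998 in amygdala over all probe sets, and no pair of arrays held identical values.

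The labels give a processing batch for every array. In hippocampus, batch 4 held 3 CS, 2 FC and 2 NH arrays, batch 5 held 4 CS and 4 FC, batch 6 held 1 CS, 2 FC and 2 NH, and batch 7 held 6 NH. In amygdala, batch 1 held 6 NH arrays, batch 2 held 3 CS, 4 FC and 3 NH, and batch 3 held 3 CS, 2 FC and 1 NH. Each tissue was fitted by itself with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the 3 arms and the batch as a fixed block. All tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. With this block, batches that hold a single arm add to the estimate of the spread but not to any difference. Every difference from NH therefore rests on the 4 NH arrays in each tissue that shared a batch with other arms. Differences between tissues were tested as contrasts in a joint fit of all 48 arrays with the same block.

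Before the data were examined, 26 gene lists with 776 entries, the rule for named genes, the designs and most alternatives were fixed. The lists covered immediate early genes, glucocorticoid-responsive genes, heat shock and cytosolic chaperones, endoplasmic reticulum chaperones, glutamate receptors, GABA genes, cAMP signalling, calcium and MAPK signalling, the synaptic vesicle, the postsynaptic density, chromatin enzymes, clock genes, ribosomal proteins, the respiratory chain and neuropeptides. The remaining lists held markers of astrocytes, oligodendrocytes, microglia, vessels, choroid plexus, blood, striatum, thalamus and hypothalamus, interneurons, hippocampal neurons and the amygdala. Lists were tested with camera at a preset correlation of 0.01, on the brightest probe set of each gene, and adjusted over 156 tests. In repeated fits of the immediate early gene list the adjustment ran over the lists of the refitted comparison alone. Camera with an estimated correlation and fry served as alternatives. A list needed at least 3 tested members. The named genes were, for each comparison, up to 10 that passed in each direction, or, where fewer than 3 passed, the 3 with the smallest unadjusted p in that direction. Added to these were Fos, Junb, Egr1, Egr2, Arc, Nr4a1, Dusp1, Btg2, Ier2, Homer1, Bdnf, Sgk1, Fkbp5, Tsc22d3, Per1 and Cdkn1a, and up to 4 members with the smallest p of each list that passed. For each test between tissues the rule took the 5 smallest p past the threshold in each direction.

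The fits were tested on simulated data for each design, with 200 of 7453 probe sets changed. At a log2 change of 0.30, recovery was 64.2% for CS minus NH, 76.1% for FC minus NH and 85.1% for FC minus CS in hippocampus, and 62.7%, 67.2% and 77.6% in amygdala. At a log2 change of 0.50 it was between 91.0% and 98.5% over the 6 comparisons, and at 1 it was 100% in each. Between 4.84% and 8.25% of simulated calls were false. The simulated noise was independent between probe sets, which need not hold for the real arrays. With fewer changed probe sets than 200 the adjusted threshold is also stricter. Recovery and false calls on the real arrays may therefore differ from these values. The number of arrays limits the precision: the median standard error of a log2 difference was 0.0569 to 0.0755 over the 6 comparisons.

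Alternatives changed the batch term, the arrays in the fit, the normalization, the filter, the variance model, array weights, the handling of several probe sets of a gene and the set test. Chosen after seeing the data were principal components as covariates, list tests between tissues, repeated fits of the immediate early gene list, refits of genes without an outlying array, a refit of the split with most calls and an exact permutation of called genes. The components were taken from batch-centred values without the immediate early genes. RNA integrity was followed by the log2 ratio of the 3' to the 5' control probe sets of Gapdh and beta-actin, compared between arms with 100000 permutations within batches. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.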

Results

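Transcript levels were measured in hippocampus from 8 CS, 8 FC and 10 NH arrays and in amygdala from 6 CS, 6 FC and 10 NH arrays. The hippocampus is needed for memory of places and contexts, and the amygdala for learned fear. The comparison of CS and FC with NH asks how each brain region responded to a behavioural session. FC minus CS sets the arm read as associative against the arm read as nonassociative. It cannot tell association apart from anything else that differed between these arms. Levels are log2 intensities, and a log2 difference of 1 is a doubling. Differences are those within processing batches, from limma with the batch as a block, and are given with their standard errors.

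Marker genes separated the tissues in the direction of their labels for most hippocampal markers. Of 16 hippocampal neuron markers with a probe set, 9 lay at a higher percentile of the array in every hippocampus array than in any amygdala array. Neurod6, a neuronal transcription factor, lay at a mean percentile of 82.2 in hippocampus and 35.0 in amygdala, Dsp, which encodes the desmosomal protein desmoplakin, at 67.3 and 17.5, and Prox1, a transcription factor of dentate granule cells, at 38.3 and 11.5. Wfs1 and Calb1 lay at a higher percentile in every amygdala array. Of 11 amygdala and piriform markers, the tachykinin gene Tac2 (61.2 in hippocampus, 78.0 in amygdala) and the cadherin Cdh13 (43.3 and 65.0) were higher in every amygdala array, and Rspo2 was higher in every hippocampus array. No test was made of these levels, because the tissues appear to have been normalized separately.

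In hippocampus, Fos was the only probe set of 7453 that differed between CS and NH. Fos, which encodes a subunit of the AP-1 transcription factor and is a standard marker of recent neuronal activity, was 1.97-fold higher in CS, a log2 difference of 0.98 ± 0.149 (SE; adjusted p = 0.00433). Its level was 6.67 ± 0.165 (SD, n = 8) in CS and 5.44 ± 0.409 (SD, n = 10) in NH. All 4 CS arrays in batches that also held NH arrays lay above every NH array of their batch. Within batches the difference was 0.98 in batch 4 and 0.85 in batch 6, which held 1 CS array, and Fos did not pass with either batch alone. A second, dim Fos probe set lay below the filter and differed by -0.03 (adjusted p = 0.9999), and none of its differences passed in any comparison. When Fos was averaged over both probe sets, or when the 60% dimmest probe sets including Fos were left out, the Fos call was lost here and in each other comparison with NH. The filter was applied after averaging, so the averaged Fos may have been left out untested.

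The immediate early genes, which are transcribed within minutes of neuronal stimulation, rose as a list in hippocampus of CS. The mean log2 difference of its 26 tested members was 0.11, with 19 members positive and 7 negative (camera, adjusted p = 5.35e-07; with an estimated correlation, adjusted p = 0.0272; in fry, which it did not pass, adjusted p = 0.104). Over all genes tested 1 member passed, and 4 passed when adjusted over the list alone: Fos, Dusp1, Junb and Nr4a1. Dusp1, a phosphatase that inactivates MAP kinases, differed by 0.39 ± 0.0829 (adjusted p = 0.224), and the orphan nuclear receptor Nr4a1 by 0.36 ± 0.0913. The AP-1 subunit Junb differed by 0.28 and the zinc finger transcription factor Egr1 by 0.20, and neither passed over all genes. Rhoa, a small GTPase that controls the actin cytoskeleton, differed by 0.29 ± 0.0620 (adjusted p = 0.224). The smallest p among lower probe sets belonged to the GTPase Gpn3 (-0.21), the receptor partner Ramp2 (-0.18) and the laminin chain Lamb1 (-0.24), none of which passed. Other probe sets of Rhoa (0.02 and 0.14) and Lamb1 (-0.03) differed by less.

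Stress hormone targets did not pass singly in hippocampus CS minus NH. Glucocorticoid-responsive genes passed as a list, with 16 of 24 members positive (camera, adjusted p = 0.0380), but not with an estimated correlation (adjusted p = 0.844). No member passed over all genes, and 1 passed when adjusted over the list alone. Its leading members were Dusp1, the mTOR inhibitor Ddit4 (0.29), the clock gene Per1 (0.16) and Nfkbia (0.12), the NF-kappaB inhibitor, of which another probe set differed by -0.01, and Dusp1 also stands on the immediate early list. Sgk1, a kinase induced by serum and glucocorticoids, differed by 0.18 and the glucocorticoid receptor cochaperone Fkbp5 by 0.06. The glucocorticoid-induced leucine zipper Tsc22d3 (-0.04), the neurotrophin Bdnf (-0.06), the cell cycle inhibitor Cdkn1a (0.02) and the antiproliferative gene Btg2 (0.09) had intervals that included 0. Without NH replicate 100 no probe set passed, and the immediate early list shifted by 0.08 (adjusted p = 0.0677). With only CS and NH arrays in the fit no probe set passed either, and Fos differed by 0.93 (adjusted p = 0.562).

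Fos was also the only probe set that differed between FC and NH in hippocampus. It was 2.12-fold higher in FC, a log2 difference of 1.09 ± 0.147 (adjusted p = 5.55e-04), at 6.78 ± 0.0918 (SD, n = 8) against 5.44 ± 0.409 (SD, n = 10). All 4 FC arrays in batches with NH arrays lay above every NH array of their batch, and the difference was 1.15 in batch 4 and 1.10 in batch 6. The immediate early list rose by a mean of 0.14, with 22 of 26 members positive (camera, adjusted p = 1.78e-09; with an estimated correlation, adjusted p = 0.00888). Of its members 1 passed over all genes, and 6 passed when adjusted over the list alone: Fos, Nr4a1, Dusp1, Junb, the zinc finger gene Klf10 and Egr1.

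Among genes that did not pass over all probe sets in hippocampus FC minus NH, Nr4a1 differed by 0.43 ± 0.0901 and Dusp1 by 0.38 ± 0.0819 (adjusted p = 0.215 for both). Junb differed by 0.34 (adjusted p = 0.573), Egr1 by 0.25 and Per1 by 0.19. Sgk1 (0.28), Btg2 (0.10), Bdnf (-0.08), Fkbp5 (0.05), Tsc22d3 (0.00) and Cdkn1a (0.01) had intervals that included 0, and Sgk1 differed by -0.05 in batch 4 and 0.76 in batch 6. The deubiquitinase Otub1 (-0.24), the unfolded protein response factor Xbp1 (-0.29) and the kinase Dyrk1a (-0.20) had the smallest p among lower probe sets, and other probe sets of Otub1 and Dyrk1a differed by -0.17 and 0.27, the latter in the opposite direction. Endoplasmic reticulum chaperones fell as a list, with 11 of 16 members negative, led by Xbp1, Hspa5 (-0.38) and Hsp90b1 (-0.15), the last 2 being luminal chaperones (camera, adjusted p = 0.0115). With an estimated correlation the list did not pass (adjusted p = 0.895), and no member passed over all genes or when adjusted over the list alone. With batch 4 alone no probe set passed, and without NH replicate 111 Nr4a1 passed too, which made 2.

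In hippocampus no probe set differed between FC and CS. In limma 57 had an unadjusted p below 0.05, where 372.7 would be expected of independent tests, and the smallest adjusted p was 0.9999. Fos differed by 0.11 ± 0.112, with a 95% interval from -0.12 to 0.34, and by 0.17, 0.03 and 0.25 in batches 4, 5 and 6. Junb differed by 0.05, Nr4a1 by 0.07, Egr1 by 0.04, Dusp1 by -0.01, Btg2 by 0.01, Sgk1 by 0.11 (0.66 in batch 6, with 1 CS array) and Per1 by 0.03. Bdnf (-0.02), Fkbp5 (-0.01), Tsc22d3 (0.03) and Cdkn1a (-0.01) lay as near to 0. The smallest p among higher probe sets belonged to the uridine-cytidine kinase Uck1 (0.10), the morphogen Shh (0.17) and the B cell factor Pax5 (0.12), and among lower ones to the actin-binding protein Lasp1 (-0.14), the cell cycle gene Rprm (-0.13) and the RNA demethylase Fto (-0.11). Other probe sets differed by 0.15 for Lasp1, the opposite direction, by -0.05 and 0.09 for Rprm, by -0.01 for Pax5 and by 0.02 for Uck1. The immediate early list had 18 of 26 members positive, a mean of 0.03 and an adjusted p of 0.103 in camera, and no member passed over all genes or when adjusted over the list alone. Blood and leukocyte markers were higher in FC, with 7 of 7 members positive and a mean of 0.07 (camera, adjusted p = 0.00667; with an estimated correlation, adjusted p = 0.844). The erythrocyte genes Slc4a1 (0.09), Epb42 (0.10) and Alas2 (0.07) and the antimicrobial peptide Camp (0.04) led it, and no member passed over all genes or when adjusted over the list alone.

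**Figure D1:**
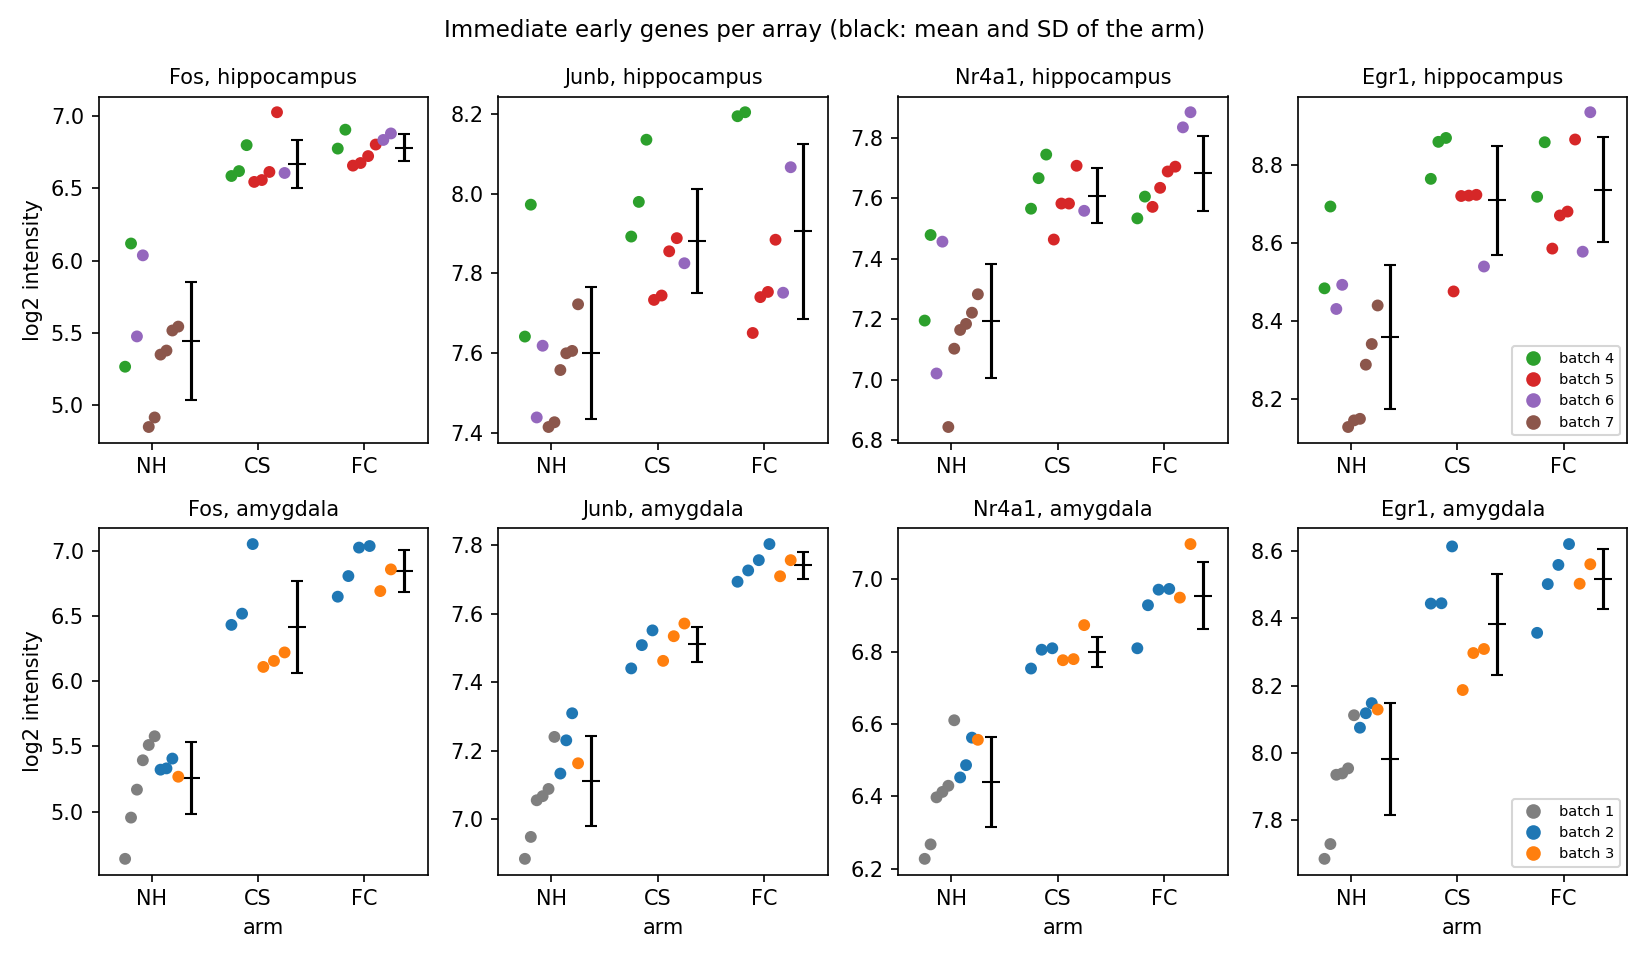
Log2 intensity of Fos, Junb, Nr4a1 and Egr1 on each array (y axis) by arm (x axis), with hippocampus in the top panels and amygdala in the bottom panels. Points are arrays coloured by processing batch, and black marks are the arm mean and SD; in amygdala all 6 CS and 6 FC arrays lie above every NH array of their batch for each of the 4 genes, and the Fos mean is 5.26 in NH, 6.41 in CS and 6.84 in FC.

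In amygdala, Fos was the only probe set that differed between CS and NH, and it was 2.22-fold higher in CS. The log2 difference was 1.15 ± 0.149 (adjusted p = 4.44e-04), at 6.41 ± 0.35 (SD, n = 6) against 5.26 ± 0.279 (SD, n = 10), and all 6 CS arrays lay above every NH array of their batch. The difference was 1.31 in batch 2 and 0.89 in batch 3, which held 1 NH array. The immediate early list rose by a mean of 0.15 over 27 members, 21 of them positive (camera, adjusted p = 3.44e-09; with an estimated correlation, adjusted p = 5.05e-04). Over all genes 1 member passed, and 11 passed when adjusted over the list alone. Besides Fos these included Junb (0.30, adjusted p over all genes 0.0905), Dusp1 (0.41, 0.121), Nr4a1 (0.27, 0.395), the polo-like kinase Plk2 (0.27), Egr2 (0.31), Egr1 (0.29) and Gadd45g (0.20).

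Other named genes did not pass in amygdala CS minus NH. Sgk1 differed by 0.26 with an interval from 0.05 to 0.47, but by 0.14 with an interval from -0.03 to 0.31 without CS replicate 23139. Btg2 differed by 0.10, Per1 by 0.11, Bdnf by 0.10, Fkbp5 by 0.06, Tsc22d3 by 0.00 and Cdkn1a by -0.11. The phosphoinositide phosphatase Mtmr14 (-0.44), the endothelial transcription factor Sox18 (-0.17) and the repeat-binding protein Cggbp1 (-0.23) had the smallest p among lower probe sets. Other probe sets differed by -0.01 for Mtmr14, -0.14 for Sox18 and -0.05, 0.00 and 0.05 for Cggbp1. Genes of protein synthesis and respiration were slightly higher as lists. Ribosomal protein genes had 20 of 24 members positive with a mean of 0.09, led by Rplp0 (0.17), Rpl13a (0.15) and Rpl10a (0.21) (camera, adjusted p = 6.03e-04; with an estimated correlation, which lost the call, adjusted p = 0.895). Respiratory chain genes had 52 of 59 positive with a mean of 0.09, led by Cox7a2 (0.23), while Atp5g1 (-0.14) went the other way (camera, adjusted p = 4.79e-06; with an estimated correlation, which lost the call, adjusted p = 0.895). No member of either passed over all genes or when adjusted over the list alone.

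Most calls came from amygdala FC minus NH, where 7 genes rose, all on the immediate early list, and none fell. Fos was 2.89-fold higher, a log2 difference of 1.53 ± 0.146 (adjusted p = 1.44e-06), at 6.84 ± 0.163 (SD, n = 6) against 5.26 ± 0.279 (SD, n = 10). Junb was 1.45-fold higher (0.53 ± 0.0573, adjusted p = 7.45e-06), Dusp1 1.45-fold (0.54 ± 0.0818, adjusted p = 0.00151) and Nr4a1 1.35-fold (0.44 ± 0.0609, adjusted p = 5.44e-04). Egr2 was 1.35-fold higher (0.43 ± 0.0820, adjusted p = 0.0231), Egr1 1.33-fold (0.41 ± 0.0755, adjusted p = 0.0195) and Gadd45g, a stress sensor that acts on MAP kinase signalling, 1.23-fold (0.30 ± 0.0543, adjusted p = 0.0195). For each of the 7 genes all 6 FC arrays lay above every NH array of their batch. The Fos difference was 1.52 in batch 2 and 1.51 in batch 3.

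The immediate early list rose in amygdala FC minus NH by a mean of 0.21, with 18 of 27 members positive (camera, adjusted p = 7.43e-15; with an estimated correlation, adjusted p = 3.75e-05). Over all genes 7 members passed, and 14 passed when adjusted over the list alone, the further ones being Dusp6 (0.39), a phosphatase of ERK, Klf10 (0.35), the survival gene Mcl1 (0.26), Btg2 (0.21), Plk2 (0.19), Gadd45b (0.18) and the AP-1 subunit Fosb (0.16). Per1 (0.26, adjusted p = 0.790) and Sgk1 (0.20) did not pass. Bdnf (-0.02), Fkbp5 (0.01), Tsc22d3 (-0.02) and Cdkn1a (-0.09) had intervals that included 0. Of lower probe sets, Mtmr14 (-0.44), the actin gene Actb (-0.34) and the replication factor Cdc45 (-0.16) had the smallest p, and none passed. Other probe sets of Mtmr14 and Actb differed by 0.04 and -0.21.

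Fos, Junb, Dusp1 and Nr4a1 passed in amygdala FC minus NH when any 1 of the 16 arrays of batches 2 and 3 was left out, whereas Egr1, Egr2 and Gadd45g each lost their call for some arrays. Without NH replicate 28892 only the first 4 passed. With batch 2 alone 2 genes passed, Fos and Junb, and with batch 3 alone 1 did, Fos. Batch 3 held 1 NH array, so the spread in that fit came from the other arms. With only FC and NH arrays in the fit, Egr2 (adjusted p = 0.0574) and Gadd45g (adjusted p = 0.0675) did not pass. A second probe set of Junb differed by 0.33 and did not pass (adjusted p = 0.0968), and the dim second probe set of Egr1 differed by -0.20 (adjusted p = 0.940). Array weights raised the count from 7 to 911, and a fit without the batch term to 211.

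No single probe set differed between FC and CS in amygdala, but the immediate early genes were higher in FC as a list. Of 27 members 21 were positive, with a mean of 0.06 and a median of 0.04 (camera, adjusted p = 6.24e-05; with an estimated correlation, adjusted p = 0.0107; fry, adjusted p = 0.0524). None passed over all genes, and 2 passed when adjusted over the list alone, Junb and Fosb. Junb differed by 0.23 ± 0.0517, with a 95% interval from 0.12 to 0.34, and by 0.25 in batch 2 and 0.21 in batch 3. Fos was 1.31-fold higher (0.38 ± 0.132, interval 0.11 to 0.66), by 0.21 in batch 2 and 0.61 in batch 3. Nr4a1 differed by 0.17 ± 0.0550, Fosb by 0.15 ± 0.0419, Per1 by 0.15, Dusp1 by 0.13, Egr1 and Egr2 by 0.12 and Btg2 by 0.11. Some of these were uneven between batches 2 and 3: Egr1 (0.01 and 0.27), Dusp1 (0.06 and 0.22), Egr2 (0.07 and 0.18) and Per1 (0.24 and 0.04). Nr4a1 (0.13 and 0.21) and Btg2 (0.10 and 0.12) were less so. Other probe sets differed by 0.15 for Junb and, below the filter, by -0.08 for Fos and -0.17 for Egr1. Oligodendrocyte markers (9 of 9 positive, mean 0.05, camera, adjusted p = 0.0957) and striatal neuron markers (5 of 5 negative, mean -0.07, adjusted p = 0.257) shifted by about as much in this comparison and did not pass. With batch 3 alone the immediate early list shifted by 0.09 (adjusted p = 0.0553) and Fos passed by itself. With batch 2 alone the list shifted by 0.04 (adjusted p = 0.0189). Both adjusted p of the list are over the lists of this comparison alone, not over all comparisons.

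Across all probe sets of amygdala FC minus CS the smallest adjusted p in limma was 0.9995, and 92 had an unadjusted p below 0.05 against 372.7 expected of independent tests. Besides Junb and Fosb the smallest p belonged to the autophagy gene Trp53inp2 (0.17) among higher probe sets, and to the oligosaccharyltransferase subunit Stt3a (-0.17), the exoribonuclease Xrn1 (-0.20) and the actin nucleation subunit Arpc5l (-0.12) among lower ones, with -0.07 and -0.06 for other probe sets of Stt3a and Arpc5l. Bdnf (-0.12), Sgk1 (-0.06), Fkbp5 (-0.05), Tsc22d3 (-0.01) and Cdkn1a (0.01) had intervals that included 0. Respiratory chain genes were lower as a list, with 50 of 59 members negative, a mean of -0.04 and Cycs (-0.12) and Cox5b (-0.13) in front (camera, adjusted p = 0.00128), and so were ribosomal protein genes, with 21 of 24 negative, a mean of -0.05 and Rpl7 (-0.15) in front (camera, adjusted p = 0.00264). With an estimated correlation neither passed (adjusted p = 0.902 and 0.895), and no member of either passed over all genes or when adjusted over the list alone.

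**Figure D2:**
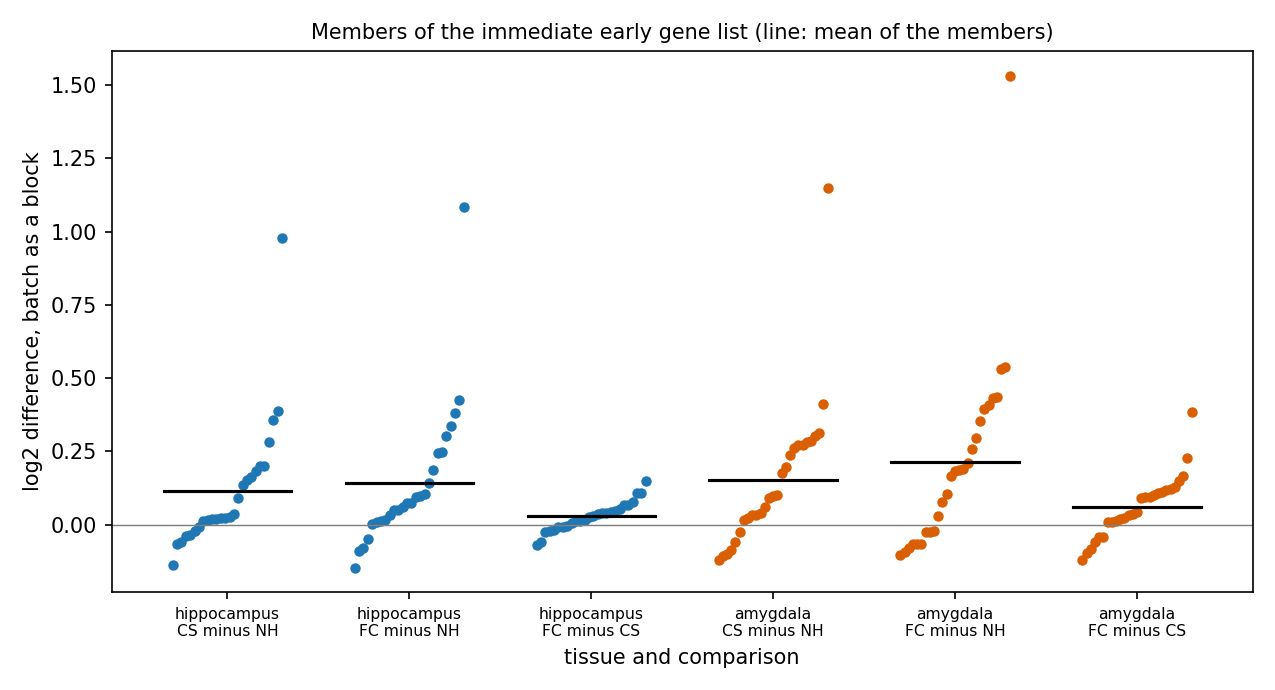
Log2 difference of each tested member of the immediate early gene list (y axis, batch as a block) in each tissue and comparison (x axis). Points are genes and lines are their means, which are 0.11, 0.14 and 0.03 in hippocampus and 0.15, 0.21 and 0.06 in amygdala; the highest point of each comparison with NH is Fos.

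No gene's response was shown to differ between the tissues. The amygdala difference minus the hippocampus difference passed for 0 probe sets in CS minus NH, FC minus NH and FC minus CS in limma. At an unadjusted p below 0.05 there were 187, 252 and 99, against 372.7 expected of independent tests. For Fos this contrast was 0.17 in CS minus NH, 0.45 in FC minus NH and 0.28 in FC minus CS, with adjusted p of at least 0.984. Junb had 0.02, 0.20 and 0.18, and Gadd45g 0.18, 0.25 and 0.07. The immediate early list did not pass between tissues either (camera, adjusted p = 0.745, 0.347 and 0.461). If the tissues share animals, their arrays are not independent of each other, which the joint fit did not model.

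Differences of CS and of FC from NH were correlated across probe sets, and comparisons that share NH arrays correlate with no effect at all. In hippocampus Pearson's r across 7453 probe sets was 0.802, where 100 simulations of unchanged arms on the same design gave a mean of 0.711. The covariance was 0.00497 against 0.00573 simulated, a difference of -7.59e-04. In amygdala r was 0.750 against 0.60 simulated, and the covariance was 0.00451 against 0.00374, a difference of 7.69e-04. With the NH arrays divided between the comparisons, r was 0.585 and 0.391 in hippocampus and 0.481 and 0.689 in amygdala, the second value with the NH arrays exchanged. Both groups of NH arrays stood in 1 fit, linked by the batch that held only NH arrays. The comparisons were thus not fully separated, and no simulation was made for this division. Probe sets are not independent replicates, and no p is given. The simulated noise, here and for the lists below, was independent between probe sets. It therefore sets no bound for arrays that share variation, and no excess is read from these values. Fos was the 1 gene called in both comparisons of each tissue. Lists as long from the simulated unchanged arms shared 0.16 probe sets on average in hippocampus and 0.25 in amygdala. Independent lists would share 1.34e-04 and 9.39e-04, which leaves out the shared NH arrays.

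Of 156 list tests 14 passed in camera, and the 5 that held with an estimated correlation were all of the immediate early list, in every comparison but hippocampus FC minus CS. In fry 3 passed. Among the others, respiratory chain genes were lower in hippocampus of CS (53 of 60 members negative, mean -0.06, adjusted p = 2.36e-05) and of FC (47 of 60 negative, mean -0.07, adjusted p = 4.79e-06) than in NH. Uqcrc2, a subunit of complex III, differed by -0.19 and -0.20, and with an estimated correlation both tests had an adjusted p of 0.895. No member passed over all genes or when adjusted over the list alone.

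The 20 lists that passed in no comparison included those for synaptic function and for other cell types. The smallest adjusted p in camera over the 6 comparisons was 0.0693 for calcium, CaMK and MAPK signalling, 0.208 for the synaptic vesicle and release machinery, 0.395 for GABA genes, 0.431 for glutamate receptors, 0.470 for the postsynaptic density scaffold and 0.685 for cAMP, PKA and CREB signalling. It was 0.208 for heat shock and cytosolic chaperones, 0.217 for neuropeptides, 0.305 for histone and DNA modifying enzymes and 0.37 for clock genes. Among cell type markers it was 0.0957 for oligodendrocytes, 0.132 for striatal neurons, 0.151 for thalamus and hypothalamus, 0.152 for microglia, 0.217 for astrocytes, 0.470 for choroid plexus and for the amygdala, 0.480 for vessels, 0.487 for interneurons and 0.50 for hippocampal neurons. No member of these 20 lists passed over all genes or when adjusted over the list alone.

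RNA integrity did not differ detectably between the arms. The log2 ratio of 3' to 5' control probe sets of Gapdh and beta-actin gave adjusted p of at least 0.853 in 12 permutation tests within batches, and the widest difference was -0.15 for beta-actin in hippocampus FC minus CS.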

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

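The list tests between tissues and the refits without an outlying array in this part were chosen only after the result was seen. Respiratory chain genes, which supply ATP, passed between the tissues with the preset correlation but not with an estimated one (adjusted p = 0.947 for both comparisons named here). Over 59 members the amygdala difference lay above the hippocampus difference by a mean log2 of 0.15 in CS minus NH (camera, adjusted p = 1.14e-11) and of 0.12 in FC minus NH (adjusted p = 1.55e-06). In CS minus NH 52 of 59 members were positive in amygdala and 53 of 60 negative in hippocampus. Ribosomal protein genes lay apart in the same sense in CS minus NH, by a mean of 0.10 over 24 members (camera, adjusted p = 0.00102; with an estimated correlation, adjusted p = 0.947). These 3 of 78 list tests passed with the preset correlation, 0 passed with an estimated correlation, and the tissues appear to have been normalized separately.

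Single arrays stood apart from the rest of their arm in 5 of 81 tests, where chance gives about 1 in 20, or 4.05. In amygdala CS, replicate 23139 of batch 2 was the highest for Sgk1 (6.67, next array 6.12) and for Dusp1 (7.46, next 7.25). In hippocampus, Btg2 was highest at 8.56 in CS replicate 31 (next 8.45), Per1 was highest at 7.18 in FC replicate 79 (next 7.06), and Dusp1 was lowest at 7.56 in FC replicate 113 (next 7.82). Without amygdala CS replicate 23139 the differences in amygdala CS minus NH were 0.14 for Sgk1, with an interval that included 0, and 0.35 for Dusp1, against 0.26 and 0.41 with it. Without that array Fos was still the 1 gene past the threshold in amygdala CS minus NH.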

How the results depend on the processing

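The fits with principal components, the refit without an outlying array, the repeated fits of the immediate early list and the leave-one-out fits of that list were chosen only after the result was seen. The planned test of amygdala against hippocampus in NH and its alternatives were not run, because the tissues appear to have been normalized separately. No pairing of arms was possible within a tissue, because the arms share no replicate number. The possible link of animals between tissues was not modelled. Where no cause is named, the cause was not tested. Ier2, Homer1 and, in hippocampus, Egr2 lay below the filter and were not tested in the main fits. Without the filter, limma gave amygdala Ier2 0.31 in CS minus NH (unadjusted p = 6.88e-05) and 0.38 in FC minus NH (2.71e-06). Hippocampus Ier2 differed by 0.16 and 0.24 (unadjusted p = 0.137 and 0.0321). The Homer1 probe sets differed by -0.05 and -0.03 in amygdala FC minus NH. Hippocampus Egr2 differed by 0.13 in each comparison with NH.

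Without the batch term the counts rose to 7 in hippocampus CS minus NH, 7 in FC minus NH, 17 in amygdala CS minus NH and 211 in FC minus NH (192 higher, 19 lower). With batch as a random block they were 4 in hippocampus FC minus NH and 4 in amygdala CS minus NH, and with array weights 3, 5 and 911 (621 higher, 290 lower) in hippocampus FC minus NH, amygdala CS minus NH and FC minus NH. With the 60% dimmest left out, Fos itself was removed, and the counts were 0 in hippocampus CS minus NH and FC minus NH and in amygdala CS minus NH (73, 105 and 210 at an unadjusted p below 0.05 in limma). Over gene means, where Fos was averaged with its dim second probe set before the filter, they were 0 in the same comparisons (77, 120 and 199). With 2 principal components they were 2 in hippocampus CS minus NH, 2 in amygdala CS minus NH and 17 in FC minus NH. With only the compared arms, hippocampus CS minus NH gave 0 (129 unadjusted).

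Single batches held few arrays, and batch 3 held 1 NH and batch 6 held 1 CS array, so other arms supplied the spread. In hippocampus CS minus NH batch 4 gave 1 and batch 6 gave 7, none of them Fos. In FC minus NH batch 4 gave 0 (116 unadjusted) and batch 6 gave 4, Fos among them, and in FC minus CS batch 6 gave 38. In amygdala FC minus NH batch 2 gave 2 and batch 3 gave 1, and in FC minus CS batch 3 gave 1, Fos. Only arrays of batches that held both arms were left out singly (12 in each hippocampus comparison with NH, 20 in FC minus CS, 16 in amygdala). The counts then ranged from 0 to 1 in hippocampus CS minus NH (0 without NH replicate 100), from 1 to 2 in FC minus NH (2 without NH replicate 111), and from 4 to 9 in amygdala FC minus NH (4 without NH replicate 28892). They stayed at 1 in amygdala CS minus NH and at 0 in FC minus CS of both tissues.

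Refits of the immediate early list were adjusted over the lists of the refitted comparison alone, not over all comparisons. On that scale the main fits had adjusted p of 8.32e-05 in amygdala FC minus CS and 0.165 in hippocampus FC minus CS. In camera with the preset correlation the immediate early list kept its sign and its side of the threshold under every refit except 3. These were batch 6 alone in hippocampus CS minus NH (0.107, adjusted p = 0.0758), the same comparison without NH replicate 100 (0.0788, adjusted p = 0.0677) and batch 3 alone in amygdala FC minus CS (0.0886, adjusted p = 0.0553). In fry it did not pass in hippocampus CS minus NH (adjusted p = 0.104) or amygdala FC minus CS (adjusted p = 0.0524). With single arrays left out the shift ranged from 0.0788 to 0.148 in hippocampus CS minus NH and from 0.0532 to 0.0674 in amygdala FC minus CS. Lists past the threshold numbered 14, but 5 with an estimated correlation, 3 in fry and 22 over gene means. The correlation of CS minus NH with FC minus NH was 0.757 without the batch term, 0.781 without the filter, and 0.585 and 0.391 with NH divided in hippocampus; in amygdala it was 0.882, 0.727, 0.481 and 0.689.

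Without its outlying array Sgk1 in amygdala CS minus NH differed by 0.142 against 0.257. The second, dim probe set of Fos differed by -0.0281 in hippocampus CS minus NH (adjusted p = 0.9999) and that of Egr1 by -0.198 in amygdala FC minus NH (adjusted p = 0.940). Named genes were refitted under 7 settings (no batch term, batch as a random block, only the compared arms, quantile normalization, median centring, trend and robust variance, array weights). Of these 931 values 3 lost and 29 gained a call, and 0 called values changed sign. Most of the 931 belonged to named values without a call, which could not lose one. Of the values that did not pass, 26 changed sign. Of 58 values from other probe sets, none that belonged to a called value passed: 4 kept its sign and 2 changed it. The counts between tissues were 0 under all 7 alternatives.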

Other observations

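The exact permutation of called genes, the 2 tests of the deficit of small p and the refit of the split with most calls were chosen only after the result was seen. In amygdala the 7 genes called in FC minus NH lay in the order NH, CS, FC, whereas Plk2, on the same list, lay 0.27 above NH in CS and 0.19 above it in FC. When the arms were permuted exactly within batches, gene by gene, the real split of FC and CS gave the widest difference of 350 splits for Junb (0.23, adjusted p = 0.0305 over 39 tests). Nr4a1 (0.17, 3 splits as large) and Gadd45g (0.10, 4 splits as large) had the same adjusted p. Fos (0.38, 10 splits as large) did not pass, with an adjusted p of 0.0520, and neither did Dusp1, Egr1 and Egr2 (0.126, 0.126 and 0.147). These genes were chosen because they were called in FC minus NH, which shares its FC arrays with this test, so they are not independent evidence. In hippocampus Fos in FC minus CS was matched by 313 of 2100 splits (exact permutation p = 0.149).

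The same permutation against NH had few splits to draw on. For the 7 genes in amygdala FC minus NH it restates their calls on the same arrays and is not given as evidence. These tests were nevertheless among the 39 adjusted together. Their small p lowered the adjusted p of the other tests, here and above. In amygdala CS minus NH, which shares its NH arrays with that selection, the real split gave the widest difference of 80 for Fos, Junb, Dusp1, Nr4a1, Egr2 and Gadd45g (exact permutation p = 0.0125, the smallest possible; adjusted p = 0.0305) but not for Egr1 (3 splits as large, adjusted p = 0.0563). In hippocampus the real split was also the widest for Fos, Dusp1, Nr4a1 and Egr1 in both comparisons with NH. Their exact permutation p was 0.0333 of 30 splits and 0.0278 of 36, the smallest possible. With an adjusted p of 0.0520 none of them passed. Gadd45g showed little there, with differences of 0.01 and 0.05 in hippocampus against 0.20 and 0.30 in amygdala. The test of that contrast between tissues did not pass for FC minus NH (unadjusted p = 0.0116, adjusted p = 0.984).

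For the higher immediate early list in amygdala of FC than of CS, only the real one of 100 within-batch splits, drawn from 350, gave so small a p in camera (1 of 100, the smallest share such a draw can give; 3.20e-06, next 3.01e-05). The share lies under 0.05 for this list by itself, without adjustment over the 156 list tests. Chance is thus made less likely but not excluded. In fry (adjusted p = 0.0524) and with batch 3 alone (adjusted p = 0.0553) the list did not pass. No single array of batches 2 and 3 carried it, since the largest p with any 1 of these 16 left out was 9.10e-04. With the 3' to 5' ratios of Gapdh and beta-actin as covariates the p was 4.58e-08 and the mean shift 0.0652 against 0.0602, which argues against RNA integrity. The treatment of the arms, the dissection and the time from session to sampling stay open as causes, and the labels do not record the last 2. Markers that bear on dissection did not pass in this comparison (oligodendrocytes, adjusted p = 0.0957; striatal neurons, 0.257), which does not exclude it.

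A deficit of small p in hippocampus FC minus CS (57 below 0.05, where 50 simulations of independent noise gave 329 to 419) may reflect variation shared by many probe sets. With the first principal component as a covariate the count was 193, and with 2 components 262, so shared variation accounts for part of it. The component held 37.7% of the batch-centred variance and showed no detectable difference between arms (permutation p from 0.519 to 0.837). Its correlation with the beta-actin ratio over 26 arrays was 0.549 (Pearson, permutation p = 0.0201, adjusted p = 0.0751 over 4 relations; Spearman's rho 0.282, p = 0.215) and 0.270 without the 2 farthest arrays, and with the Gapdh ratio 0.506 (p = 0.0376, adjusted p = 0.0751) and 0.299 without them. Within 3 batches of at least 6 arrays the sign differed for beta-actin (size 0.141 to 0.861) and was the same for Gapdh (0.180 to 0.690), so RNA integrity cannot be told apart from other sources of the component. The deficit was not particular to hippocampus FC minus CS. Against 372.7 expected of independent tests, limma gave 108 in hippocampus CS minus NH and 169 in FC minus NH. In amygdala it gave 292 in CS minus NH and 92 in FC minus CS, but 384 in FC minus NH.

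In amygdala FC minus NH, 211 probe sets passed without the batch term and 7 of them with it. The NH arrays processed in a batch of their own are a candidate cause. Over these 211 the median difference with the block was 58.7% of that without it (0.14 against 0.24), while the median standard error was 0.0603 against 0.0584, and the sign was kept in 211. Among NH arrays alone, 550 probe sets differed between the 6 arrays of batch 1 and the 4 others, which shows a batch difference with no arm involved, and 202 of the 211 moved in the same sense. The 211 were selected on those arrays, and 58.7% lies between the bounds set beforehand, so batch and arm cannot be told apart for the genes lost with the block.

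Counts were also set against other within-batch splits of the same arrays. In hippocampus FC minus NH 1 of 36 splits gave as many as the real 1 (highest other 0). In amygdala FC minus NH 3 of 100 gave as many as the real 7 (highest other 189). Each share lies under 0.05 for that count by itself, without adjustment over the counts, so chance is made less likely but not excluded. For Fos in hippocampus FC minus NH the smallest possible share is 1 of 36. The share was over 0.05 for the real count of 1 in hippocampus CS minus NH (5 of 30 splits, highest other 195) and in amygdala CS minus NH (5 of 80, highest other 15). Chance is not excluded for these counts either. For counts of 0 such a share says nothing, since each of 100 splits must give as many; the highest others were 8 in hippocampus FC minus CS, 2396 in amygdala FC minus CS and 1122, 100 and 4 between tissues in CS minus NH, FC minus NH and FC minus CS. A split that calls 2396 probe sets may reflect a structure among the amygdala arrays beyond their batches, though it is the extreme of 100 splits. That split followed the first principal component of the batch-centred values (r = 0.807 in size over 12 arrays, against 0.0409 for the real arms) and called 0 with the component as a covariate. The split was picked for its calls and lies near the component, so this loss was largely set beforehand and is no further evidence. The component held 39.3% of the variance, and its relation to the Gapdh and beta-actin ratios did not pass (adjusted p = 0.592 and 0.481), so its source stays open. For the 14 list tests past the threshold 59 of 100 shuffles gave as many (highest other 30), so chance is not excluded for that count.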
